A study of Rattus norvegicus with 4 samples.

How the data were processed

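RNA was measured in the urinary bladder muscle of female Sprague Dawley rats, with 1 bladder in each of 4 groups: a normal control and animals at 3, 7 and 25 days after spinal cord injury. Per the labels' protocols, bladders were taken under halothane, the muscle layer was dissected and frozen, and total RNA was extracted with Trizol and column-purified. Per the labels, cDNA was transcribed in vitro into biotin-labelled cRNA, so each array has 1 colour and 1 sample. The study's design text describes the arrays as an initial screen and names remodeling, inflammation and infection as later questions.

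The deposited values are 1 linear intensity per probe set, for 8799 probe sets on each of the 4 arrays, all above 0. A probe set is a group of short oligonucleotides that together read 1 transcript. Leaving out the highest and lowest 2% of values, the mean intensity was 500.9 for control, 501.1 for day 3, 500.9 for day 7 and 501 for day 25, so the deposited values had already been scaled to one target. The software, its background step and its summary method are not given in the sources used here. No detection calls were used, so it is not known for a dim probe set whether the software had called it present.

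Intensities were put on the log2 scale and each array was centred on the median of all its probe sets. This second scaling moves the arrays relative to each other. As deposited, the median log2 intensity was lower than on the control array by a difference of -0.31 at day 3, -0.03 at day 7 and -0.25 at day 25, and all changes below are relative to these medians. After centring, bright genes lay higher than dim genes at day 3, where the median change was 0.47 among the 689 brightest genes and -0.01 among the 1600 dimmest. Gene lists were for this reason compared with random lists of matched level. Values under a floor were set to the floor, the 40th percentile of all centred values of the 4 arrays, an intensity of 93.0. Of 92 values from 23 control probe sets for transcripts that a rat sample without added bacterial poly(A) RNA should lack, 6 lay above the floor. Where a gene was at the floor on 1 of the 2 arrays compared, the fold is a lower bound for the probe set read for that gene and is written "at least". Where it was at the floor on both arrays, no fold is given.

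Of the 8740 probe sets left without the array's own controls, 7006 were paired with 1 gene symbol by the platform annotation, 308 with several and 1426 with none. No gene was named from the latter groups. Symbols were updated through the gene identifier to the RefSeq table of the rat assembly GRCr8, where 6985 of the single-symbol probe sets matched. No genomic coordinates are given, because the build behind the probe sets is not given in the sources used here. The 7006 probe sets read 4736 genes, and each gene was read from its probe set with the highest mean log2 intensity over the 4 arrays. For 1565 genes there was more than 1 probe set.

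With 1 array per group there is no replicate spread, no test and no p-value, and each fold compares 2 bladders. The number of arrays limits the precision. The only measure of error within these arrays is the difference between 2 probe sets of the same gene. It gave an SD of 0.61 on the log2 scale for 1 probe set's change at day 3, 0.59 at day 7 and 0.61 at day 25, or about 1.5-fold. It covers probe differences and not differences between animals. Genes at least 2-fold higher or lower were counted for each day against control and for day 25 against day 3.

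Before the data were examined, 20 pathway lists and 12 cell type marker lists were fixed. Some lists share genes, so their medians are not separate evidence. Lyz2 is in the macrophage and response to bacteria lists, and Ctss in the macrophage and antigen presentation lists. A list's median log2 change over its members above the floor on at least 1 of the 2 arrays was placed among 10000 random lists of the same size, matched on deciles of mean level. A list is said to stand apart where its median lay outside the central 95% of the random lists, and a list with fewer than 5 such members was not placed. Over the 3 days there were 92 such list values, of which about 4.6 would stand apart by chance if the members of a list varied independently. The percentile describes the 2 arrays compared and is not a p-value.

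The genes named in the text were chosen by a rule fixed at the same time, which took 163 genes. It took the 12 largest increases and 12 largest decreases at each day against control, and 8 of each for day 25 against day 3, among genes above the floor on both arrays. It also took, of each fixed list, up to 4 members with the largest change of at least 2-fold at any day, and a set of genes named whatever their values. Some of that set, among them Cd68, Upk1b, Upk2, Gapdh and Ppia, had 0 probe sets paired with that symbol alone, so they are not reported as genes. Where a gene named as at least 2-fold changed had another probe set above the floor on both arrays that went the other way, the text says so. Another probe set that changed little in the same direction is not always pointed out.

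The same functions were tested on simulated arrays for day 3 against control, built from the real levels of the 4736 genes, with 200 genes changed by known folds and noise drawn from the spread between the day 7 and day 3 arrays. The 200 genes were drawn from those whose mean log2 level lay more than 2-fold above the floor. The shares recovered therefore do not cover dimmer genes. Of 50 genes per size, 52% of those changed 2-fold, 76% of those changed 3-fold, 86% of those changed 4-fold and 94% of those changed 8-fold came out past 2-fold in the right direction. Of the unchanged genes, 25.8% also came out past 2-fold at that noise, which holds any real difference between day 7 and day 3 and so is an upper estimate for that pair of arrays. It does not hold what sets the control array apart. Of 200 lists of unchanged genes, 5.5% stood apart. These lists were drawn at random with independent noise, so such a share follows from how they were built. It does not cover lists whose genes vary together.

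Alternatives planned before the data were examined were floors at the 20th and 60th percentiles, the values as deposited, quantile normalization, cyclic loess, the mean of all probe sets of a gene, only genes above the floor on both arrays, and a threshold of 3-fold. Another 2 were added after the data had been seen: centring on the median of probe sets above the floor on all 4 arrays, and the counts over all days without day 25. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for quantile normalization and cyclic loess.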

Results

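Gene expression was measured on 4 one-colour oligonucleotide arrays, 1 for the bladder muscle of each of 4 rats: an uninjured control and animals 3, 7 and 25 days after spinal cord injury, which cuts the bladder off from the brain's control of voiding. The comparisons ask how bladder muscle expression differs from normal at each time and between early and late times, with remodeling, inflammation and infection as the processes of interest to the study. Between 3157 and 3197 of 4736 genes lay above the floor on each array. There were no replicates, so folds describe single bladders and no difference could be set against the spread between animals. Where a gene had 2 probe sets above the floor, a gene at least 2-fold changed by its brighter one changed in the same direction by the other in 158 of 190 cases at day 3, 76 of 107 at day 7 and 87 of 112 at day 25.

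The arrays also differed in a sign of RNA quality. Probe sets at the 3′ and 5′ ends of the Gapdh transcript gave an intensity ratio of 1.05 on the control array, 2.03 at day 3, 4.09 at day 7 and 7.02 at day 25. For beta-actin the ratio was 23.1, 30.5, 50.5 and 70.9. Between the 3′ end and the middle of the transcript, the Gapdh ratio did not rise, at 1.01, 1.01, 0.90 and 0.93. That of beta-actin was 0.72, 1.81, 3.90 and 3.74.

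At day 3, the medians of the macrophage, sterol synthesis and immediate early lists lay above those of matched lists in the comparison with the control bladder, and that of detrusor receptors and ion channels lay below. Among single genes, Eln, which encodes the elastin of elastic fibres, was 14.3-fold higher, with a median-centred intensity of 2280 on the control array and 32507 at day 3. Lox, the enzyme that cross-links collagen and elastin, was 9.11-fold higher, and Timp1, an inhibitor of matrix metalloproteinases, 8.71-fold higher. Lyz2, the lysozyme of macrophages and neutrophils, was 12-fold higher and the monocyte chemokine Ccl2 was 8.70-fold higher. On the other side, the phospholipase gene Pla2g2a was 20.2-fold lower and Tacr2, the neurokinin receptor through which tachykinins contract bladder muscle, was 11.5-fold lower.

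The other genes with the largest increases at day 3 were Krt5 at 11.5-fold and Krt4 at 9.62-fold, both keratins of stratified epithelium. Thy1 was 10.1-fold, the immediate early gene Nr4a1 9.04-fold, Uchl1 8.87-fold, Cd74, the invariant chain of class II antigen presentation, 8.70-fold and Plat, tissue plasminogen activator, 8.07-fold higher. The other large decreases were Sult5a1 at 11.6-fold, Cd59b at 10.7-fold, the actin-binding protein gene Nexn at 10.5-fold, Id2 at 8.96-fold and C17h5orf24 at 8.46-fold. Pln, phospholamban, the regulator of the sarcoplasmic calcium pump, was 8.42-fold lower, the clock gene Nr1d1 7.55-fold, Ppp1r12a, the targeting subunit of myosin phosphatase, 7.53-fold, Abcd3 7.40-fold and Pcp4 6.95-fold lower. The fold for Abcd3 is that of the probe set read for it, and another of its probe sets went only from 771 to 691. Tgfb1 was at the floor in the control bladder and at least 11.4-fold higher at day 3.

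Of 15 fibrillar collagen and collagen-processing genes compared, 8 were at least 2-fold higher and 1 at least 2-fold lower, and the list median of 1.05 (log2) lay at percentile 98.58 of matched random lists. Its members included Loxl1 at 4.74-fold, Pcolce at 3.41-fold and Col12a1 at 3.33-fold higher, whereas Col1a1 was 1.70-fold and Col3a1 1.76-fold higher, close to the difference between probe sets of 1 gene. Of 6 elastic fibre genes, 3 were at least 2-fold higher and 1, Efemp1, was 2.59-fold lower, with the median of 1.15 inside the range of random lists, and with the floor at the 20th percentile that median was 0.04. Matrix proteases and their inhibitors stood apart at percentile 99.94, with 9 of 18 at least 2-fold higher, Mmp23 at 5.67-fold among them. Of 19 basement membrane and other matrix genes, 7 were at least 2-fold higher, including Thbs4 at 7.14-fold, Vcan at 5.35-fold and Bgn at 3.86-fold, and 3 were at least 2-fold lower. That list, with a median of 0.60, did not stand apart, and with the mean of all probe sets of a gene the collagen and protease lists did not either.

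Of 13 monocyte and macrophage markers compared at day 3, 9 were at least 2-fold higher and 0 lower, with a median of 1.52 and percentile 99.99. Coro1a was at least 7.06-fold, Ctss 2.87-fold and Ccr1 2.13-fold higher. Of 16 antigen presentation genes, 8 were at least 2-fold higher and 0 lower, with a median of 1.10 and percentile 99.97. RT1-Bb was 4.05-fold and RT1-Db1 3.59-fold higher. Urothelial markers, which the dissected muscle layer should hold little of, had 6 of 11 members at least 2-fold higher and 0 lower, a median of 1.01 and percentile 99.44. Krt14 was 5.66-fold and Krt8 2.95-fold higher. Antigen presentation genes no longer stood apart with the floor at the 60th percentile, nor urothelial markers with the floor at the 20th. Genes of the response to bacteria, complement and acute phase stood apart narrowly, at percentile 97.70 with 5 of 24 at least 2-fold higher, and not under 6 of 7 alternatives. Inflammatory cytokines and mediators, with 6 of 29 higher and 3 lower, did not. In that list Nos2, inducible nitric oxide synthase, was 4.35-fold higher by its brightest probe set, while the mean of its 4 probe sets was at the floor on both arrays. The eosinophil chemokine Ccl11 was at least 6.17-fold lower and Il1b differed 1.05-fold.

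Of 15 sterol synthesis genes, 10 were at least 2-fold higher at day 3 and 0 lower, and the median of 1.55 lay above all 10000 random lists. Fdps was 6.76-fold, Cyp51 4.62-fold, Acat2 3.98-fold and Mvd at least 5.75-fold higher. Of 25 immediate early and stretch-response genes, 11 were at least 2-fold higher and 0 lower, with percentile 99.975. Junb was 5.72-fold and Egr2 at least 6.73-fold higher, and Fosl2 was at least 6.14-fold higher, although another of its probe sets was lower.

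Detrusor receptors and ion channels stood apart in the other direction. Of 26 compared, 8 were at least 2-fold lower and 1 higher, and the median of -0.61 lay below all 10000 random lists. Besides Tacr2 and Pln, Gucy1a1, a subunit of the nitric oxide receptor, was 2.25-fold lower and Adrb3, a receptor that relaxes the detrusor, 2.06-fold lower. The muscarinic receptor Chrm3 was 1.75-fold lower, P2rx1, the ATP-gated channel of bladder smooth muscle, differed 1.02-fold, and Chrm2 was at the floor on all 4 arrays by the probe set read for it, with another probe set above the floor at day 3 alone. The median of 30 mitochondrial respiratory chain genes was -0.06 and lay below matched lists at percentile 0.26, although only 1 of them, Cox6c, was at least 2-fold lower, and another of its probe sets was higher.

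Smooth muscle contractile and cytoskeletal genes did not stand apart at day 3. Their median was 0.05, and negative under all 4 other scalings, with 3 of 19 at least 2-fold higher and 2 lower. Acta2, smooth muscle actin, was 2.95-fold higher by the probe set read for it, but its log2 change went from 1.56 to 0.92 under cyclic loess. Of its other probe sets, 1 went from 24962 to 64216 and 1 only from 21153 to 24563. Des, the desmin of muscle intermediate filaments, was 1.85-fold higher and Myh11, smooth muscle myosin heavy chain, 1.74-fold lower, and its log2 change of -0.80 became -1.41 under quantile normalization. Pde5a was at least 2.80-fold higher and Cald1, caldesmon, 5.14-fold lower.

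At day 3, 550 of 3554 genes, or 15.5%, were at least 2-fold higher and 380, or 10.7%, at least 2-fold lower, so 59.1% of these genes were higher. That split depended on the scaling, with 355 higher and 577 lower in the values as deposited, 425 and 444 after quantile normalization, 431 and 438 after cyclic loess, and 433 and 450 when centred on probe sets above the floor on all arrays. With the floor at the 20th percentile there were 822 and 650, and at the 60th 372 and 191. Of the unchanged genes in the simulated arrays, 25.8% came out past 2-fold, an upper estimate for the noise between the day 7 and day 3 arrays. The main counts do not clearly exceed that share. The Gapdh 3′ to 5′ ratio was 2.03 on this array against 1.05 in the control.

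**Figure D1:**
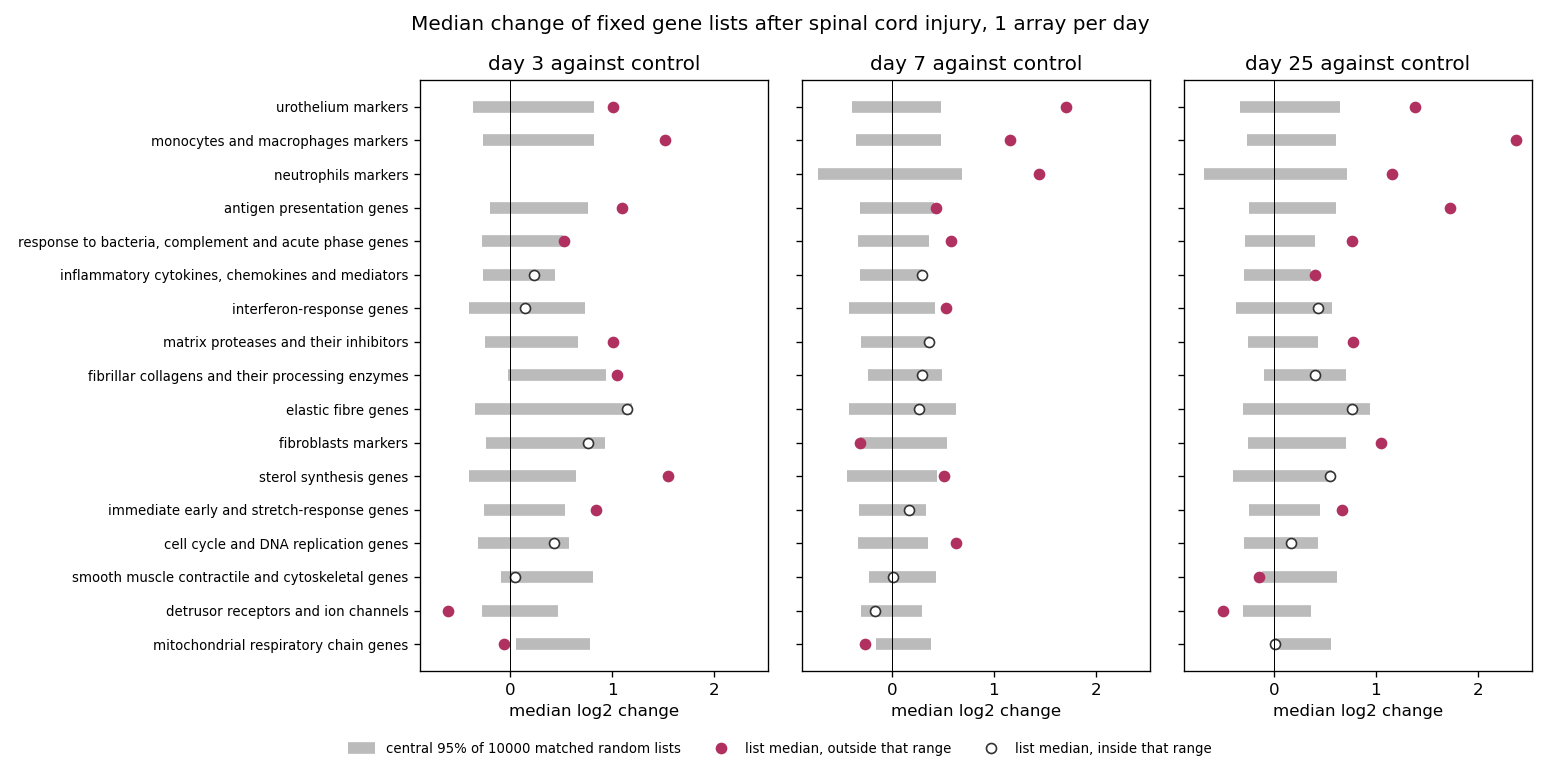
Median log2 change of 17 fixed gene lists against the control array at days 3, 7 and 25, with 1 panel per day. Points are list medians and grey bars the central 95% of 10000 random lists matched on level, filled points lying outside that range. Macrophage markers, at 1.52, 1.16 and 2.37, and urothelial markers, at 1.01, 1.70 and 1.39, lie to the right of the bars on all 3 days.

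At day 7, the medians of the urothelial, macrophage, neutrophil and cell cycle lists lay above those of matched lists in the comparison with the control bladder. Lyz2 was 12.8-fold, Krt5 8.99-fold and Krt4 7.95-fold higher. Top2a, the DNA topoisomerase of dividing cells, was 7.81-fold and Cdc20, a regulator of mitotic exit, 6.31-fold higher. S100a8 and S100a9, the calprotectin subunits of neutrophils, were at the floor on the control array and at least 15.8-fold and at least 31.1-fold higher at day 7. The glycolytic enzyme Aldoa was 13.7-fold lower. Its intensity fell from each array to the next while the Gapdh 3′ to 5′ ratio rose, so loss of 5′ signal cannot be told apart from a change after injury.

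The remaining large increases at day 7 were Uchl1 at 7.74-fold, the fatty acid binding protein Fabp5 at 7.01-fold, Thy1 at 6.90-fold, the protease inhibitor A2m at 6.09-fold, Cdo1 at 5.98-fold, Timp1 at 5.78-fold and the lipopolysaccharide-binding protein Lbp at 5.76-fold. Another A2m probe set was lower, and another of Cdo1 went only from 189 to 220. The remaining large decreases were Tmtc3 at 8.32-fold, the chemokine Cxcl14 at 7.44-fold, the clock genes Bhlhe41 at 7.14-fold and Nr1d1 at 6.20-fold, Cald1 at 6.99-fold, Pln at 6.38-fold, Pla2g2a at 5.72-fold, Efemp1 at 5.01-fold, Lipe, the hormone-sensitive lipase, at 4.73-fold by the probe set read for it, Nptx2 at 4.66-fold and Igfbp3 at 4.57-fold. Other probe sets of Nptx2 and Lipe were higher, that of Lipe from below the floor to 255.

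Of 12 urothelial markers compared at day 7, 9 were at least 2-fold higher and 1 lower, and the median of 1.70 lay above all random lists. The medians of 12 macrophage markers, at 1.16 with 6 at least 2-fold higher, and of 6 neutrophil markers, at 1.44 with 4 higher, also lay above all of them. Cell cycle and DNA replication genes stood apart at percentile 99.97, with 7 of 23 at least 2-fold higher and 2 lower. Racgap1, a gene of cytokinesis, was 4.51-fold higher, whereas Ccne1, a cyclin of S-phase entry, was at least 5.07-fold lower by the probe set read for it and near its control level by another, at 178 and 175. Response to bacteria, complement and acute phase genes, at percentile 99.95 with 7 of 22 higher and 1 lower, stood apart as well. So did interferon-response genes, at percentile 99.22 with 3 of 14 higher. In that list Irf7 was at least 4.83-fold higher by the probe set read for it, and its other probe set went from 135 to 246. Antigen presentation genes stood apart at percentile 98.245 with 5 of 17 higher and 1 lower. In that list Cd74 was 4.08-fold higher, while RT1-Bb was 2.60-fold lower by its brightest probe set and higher by another. Sterol synthesis genes stood apart at percentile 98.655, with 3 of 15 higher and 1 lower and Cyp51 2.99-fold higher by its brightest probe set and lower by another. With the floor at the 60th percentile neither of these lists stood apart, and with the mean of all probe sets of a gene the sterol list did not.

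Mitochondrial respiratory chain genes lay below matched lists at day 7, with a median of -0.27 and percentile 0.22, and 1 of 30, Cox5a, at least 2.01-fold higher. Fibroblast markers had a median of -0.32 and percentile 2.25, which became 48.38 with the mean of all probe sets of a gene, and their members did not move together: Vim was 2.21-fold and Thy1 6.90-fold higher and Igfbp6 3.47-fold lower. The 5 erythroid genes had a median of -0.74 and percentile 1.42, with Slc4a1 2.23-fold lower and the globin Hbb 1.87-fold lower. Fibrillar collagen, elastic fibre and detrusor receptor lists did not stand apart at day 7, with medians of 0.29, 0.26 and -0.16, but the elastic fibre list did with the floor at the 20th percentile, with a median of 0.97, and the detrusor list with the floor at the 60th, with a median of -0.33. Among their members Eln was 3.33-fold and Lox 3.80-fold higher, and P2rx1 2.17-fold, Gucy1a1 4.44-fold, Adrb3 2.10-fold and Chrm3 2.10-fold lower, the last with another probe set higher. Matrix proteases at percentile 97.27, inflammatory mediators at 97.28 and other matrix genes at 97.30 lay just inside the range of random lists, and each lay above it under several alternatives. Il1b was 2.88-fold, Spp1 at least 6.76-fold and Tgfb1 at least 8.02-fold higher.

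Nerve and skeletal muscle genes held single large differences at day 7 without standing apart as lists, except that the skeletal muscle list lay lower with the floor at the 60th percentile and centred on probe sets above the floor. The neurofilament gene Nefl was at least 7.36-fold lower, and of the skeletal muscle genes Tcap was at least 4.44-fold and Ckm 3.45-fold lower while Acta1 was 2.69-fold higher. At day 7, 307 of 3564 genes were at least 2-fold higher and 322 at least 2-fold lower, and 48.8% of these were higher. With the floor at the 20th percentile there were 581 and 587, and at the 60th 158 and 147. The Gapdh 3′ to 5′ ratio on this array was 4.09 against 1.05 in the control.

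At day 25, the medians of the macrophage, antigen presentation and response to bacteria lists lay above those of matched lists in the comparison with the control bladder, and that of the detrusor receptor list again lay below. Lyz2 was 28.1-fold higher, from an intensity of 579 to 16277. Mmp7, the matrix metalloproteinase matrilysin, was 14.5-fold and Plat 12.1-fold higher, and the chemokine that attracts B cells, Cxcl13, was 9.33-fold higher. The class II genes Cd74, RT1-Db1 and RT1-Bb were 9.03-fold, 8.55-fold and 7.57-fold higher. The value for RT1-Bb is that of the probe set read for it. Another of its probe sets went from 233 to 585, and the rest were at the floor on both arrays. Nr1d1 was 7.70-fold, Igfbp3 7.15-fold and Pln 6.77-fold lower.

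Krt4 was 10.2-fold, the sodium pump subunit Atp1b1 7.77-fold, Timp1 7.04-fold, Vmp1 6.93-fold and Fabp5 6.80-fold higher at day 25. Lower were Med25 at 7.14-fold, Nr1d2 at 5.69-fold, Ide, the insulin-degrading enzyme, at 5.28-fold, the urea transporter Slc14a1 at 5.06-fold, Tpm4 at 5.01-fold, Grhpr at 4.96-fold, Supt5h at 4.55-fold, Tacr2 at 4.41-fold and Ythdf3 at 4.40-fold. Other probe sets of Tpm4 and Supt5h were higher, and another of Slc14a1 went only from 115 to 114.

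Of 14 macrophage markers compared at day 25, 12 were at least 2-fold higher and 0 lower, with a median of 2.37 above all random lists. Coro1a was at least 9.21-fold, Ctss 6.57-fold and Ccr1 6.53-fold higher. Antigen presentation genes, with 10 of 16 at least 2-fold higher, 0 lower and a median of 1.73, and urothelial markers, with 7 of 12 higher, 0 lower and a median of 1.39, also lay above all random lists. Krt5 was 6.71-fold higher. Neutrophil markers stood apart at percentile 99.84, with 3 of 6 higher. S100a9 was at least 30.7-fold and S100a8 at least 16.1-fold higher. Of 25 response to bacteria, complement and acute phase genes, 10 were at least 2-fold higher and 1 lower, with percentile 99.99. Lcn2, lipocalin, which withholds iron from bacteria, was at least 10.2-fold and Lbp 4.38-fold higher. Inflammatory cytokines and mediators stood apart at percentile 98.585, with 8 of 29 higher and 1 lower, but not with the mean of all probe sets of a gene. Il1b was 5.24-fold higher, Ccl2 3.85-fold higher and Ccl11 4.04-fold lower. The interferon-response list did not stand apart except with the mean of all probe sets, although Irf8 was 4.49-fold higher. Irf7 was at least 7.41-fold higher by the probe set read for it, and its other probe set went from 135 to 260.

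Matrix proteases and their inhibitors stood apart at day 25 at percentile 99.99, with 9 of 22 at least 2-fold higher and 1 lower, and fibroblast markers at percentile 99.91, with 6 of 11 higher and 0 lower. Sfrp4 was at least 8.75-fold and Vim 3.19-fold higher. Fibrillar collagen genes had a median of 0.41 and elastic fibre genes of 0.76, both inside the range of random lists except elastic fibre genes with the mean of all probe sets, at percentile 98.24, with Eln 5.13-fold and Lox 3.99-fold higher. Immediate early and stretch-response genes stood apart at percentile 99.89, with 9 of 24 higher and 1 lower, but not with another floor or the mean of all probe sets. Tgfb1 was at least 7.86-fold and Tgfb3 3.11-fold higher, and Spp1 at least 4.43-fold higher.

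Detrusor receptors and ion channels had 6 of 27 members at least 2-fold lower, 0 higher and a median of -0.50 at percentile 0.15. Adrb3 was 3.76-fold and P2rx1 2.82-fold lower, and Chrm3 1.61-fold lower. Smooth muscle contractile and cytoskeletal genes had a median of -0.15 at percentile 1.73, although 17 of the 18 compared were within 2-fold and only Cald1 was lower, by at least 12.7-fold. Their standing apart was lost under all 4 other scalings. Acta2 was 1.17-fold and Des 1.09-fold higher, and both were slightly lower than control under cyclic loess and as deposited, and Des also after quantile normalization. Myh11 was 1.19-fold lower.

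At day 25, 415 of 3530 genes were at least 2-fold higher and 258 at least 2-fold lower, or 61.7% higher. The values as deposited gave 289 higher and 430 lower, quantile normalization 346 and 329, cyclic loess 365 and 305, and centring on probe sets above the floor on all arrays 348 and 325. The main shares, 11.8% higher and 7.3% lower, do not together exceed the 25.8% of unchanged genes past 2-fold in the simulated arrays for day 3. The Gapdh 3′ to 5′ ratio was 7.02 on this array against 1.05 in the control, and the higher urothelial and macrophage markers stood beside every other list difference on it.

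**Figure D2:**
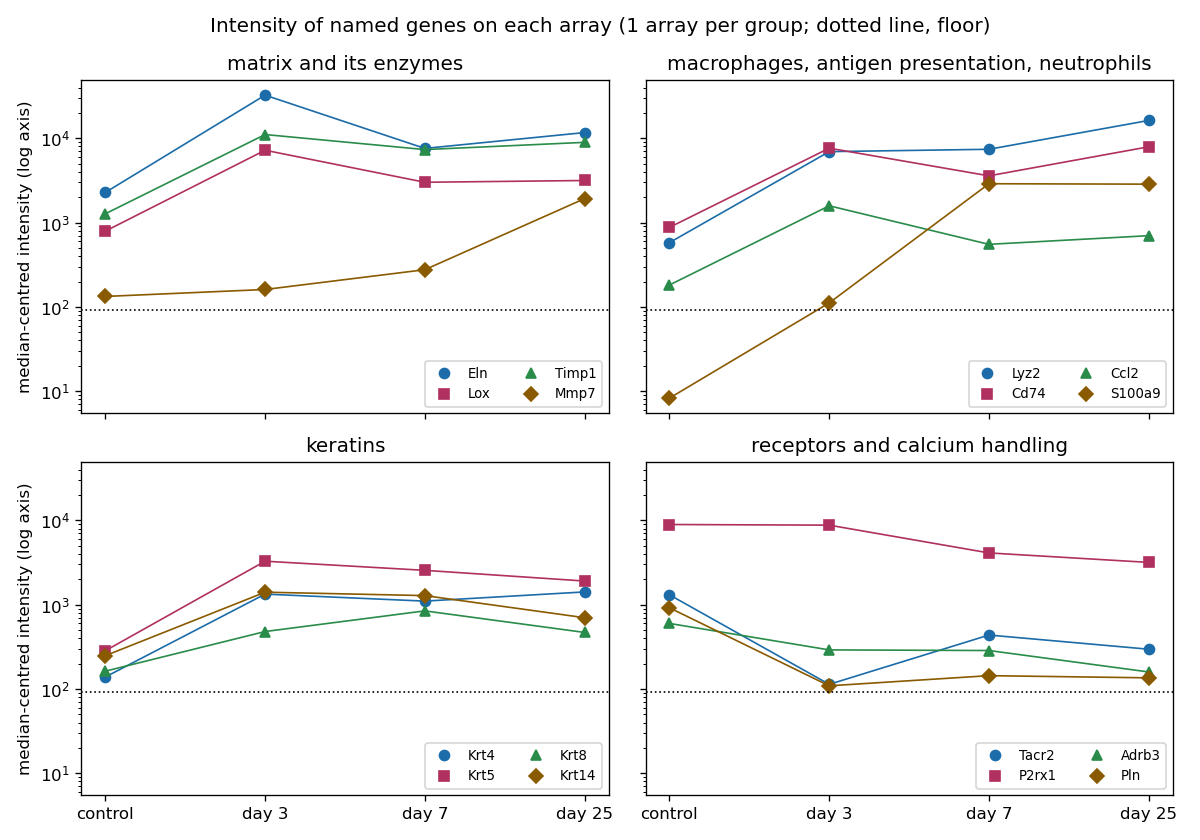
Median-centred intensity on a log axis of 16 named genes on the control array and at days 3, 7 and 25, with 1 array per group and lines joining the arrays of a gene. The dotted line is the floor at 93.0. S100a9 goes from below the floor to 2891 at day 7 and 2857 at day 25, and Tacr2 from 1308 on the control array to 113 at day 3.

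Comparing the late with the early injured bladder leaves out the control array. From day 3 to day 25, the medians of the macrophage and antigen presentation lists lay above those of matched lists, and those of the fibrillar collagen and sterol synthesis lists lay below. Among single genes, S100a9 was 25.6-fold, Mmp7 12-fold and Lcn2 8.64-fold higher at day 25. The probe set read for Crp was 7.75-fold higher. Other probe sets paired with Crp differed, going from 413 to 2461 and only from 147 to 158 between day 3 and day 25. Their pairing with Crp is that of the platform annotation and was not checked against their sequences, so an increase of Crp itself is not established. Actc1, the cardiac type actin, was 11.7-fold, Nr4a1 8.32-fold and Nos2 5.15-fold lower, the last with another probe set higher.

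The other large increases from day 3 to day 25 were the calcium channel subunit Cacna2d1 at 10.4-fold, the cyclin Ccnd2 at 10.03-fold, Pla2g2a at 9.64-fold and Cd59b at 7.95-fold, and the other large decreases were Med25 at 7.01-fold, Triobp at 6.29-fold, Tpm4 at 6.25-fold, Or1f32 at 5.19-fold and the nucleoside transporter Slc29a1 at 5.04-fold. The median of 15 fibrillar collagen genes was -0.91 and lay below all random lists, with 4 at least 2-fold lower. Elastic fibre genes lay lower at percentile 1.82, with Eln 2.78-fold lower, and sterol synthesis genes at percentile 0.03, with 7 of 15 at least 2-fold lower. Smooth muscle contractile genes, with a median of -0.52 at percentile 1, and immediate early genes, at percentile 0.725, were also lower. The elastic fibre list did not stand apart with the floor at the 20th percentile, where it lay at percentile 14.86, after quantile normalization or with the mean of all probe sets, and the smooth muscle list not with the floor at the 60th, where its median was -0.25, after quantile normalization or cyclic loess, or with the mean of all probe sets. Higher were macrophage markers at percentile 99.915, antigen presentation genes at 99.94, neutrophil markers at 99.98, inflammatory mediators at 99.93, T and NK cell markers at 98.97, heat shock and unfolded protein response genes at 99.99, and detrusor receptors at 98.00. Of these, detrusor receptors lost their place under both other floors, at percentiles 87.805 and 88.03, and under cyclic loess, neutrophil markers with the floor at the 60th percentile, and inflammatory mediators with the mean of all probe sets. Response to bacteria genes at percentile 78.13, basement membrane and other matrix genes at 46.43 and matrix proteases at 69.84 lay inside the range of random lists, the first above it with the floor at the 60th percentile, at percentile 97.975. The cytotoxic T cell gene Cd8a was 2.61-fold and the chaperone Hspa5 1.63-fold higher. In total, 335 of 3520 genes were at least 2-fold higher at day 25 than at day 3 and 309 at least 2-fold lower, or 52.0% higher, which the values as deposited moved to 344 and 238, or 59.1%. These main counts, 9.5% and 8.8% of the genes, also do not together exceed the simulated 25.8%.

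The 3 comparisons with control were then set against each other. On all 3 days, 128 of 3301 genes were at least 2-fold higher and 75 at least 2-fold lower. Independent lists would share 4.54 and 2.90. Because all 3 share the control array, 100 simulations of unchanged arrays were run, and they gave a mean of 51.7 higher, with 74 as the most, and a mean of 136.5 lower. The noise was drawn from the spread between the day 7 and day 3 arrays. It holds any real difference between them, so it is an upper estimate for that pair of arrays. It does not hold what sets the control array apart from the others, such as its Gapdh 3′ to 5′ ratio of 1.05 against 2.03, 4.09 and 7.02. The 75 genes lower on all days were fewer than the simulated mean, but with such noise this cannot be read as a deficit. The count of 75 also moved with the floor and the scaling, as given below. Part of the genes higher on all days may come from the single control bladder. Timp1, Lyz2, Krt4, Krt5, Cd74, Plat, Fabp5, Lox, Eln and Vmp1 were at least 2-fold higher on all 3 days, and Nr1d1, Pln, Tacr2, Igfbp3 and Id2 at least 2-fold lower.

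Of the other genes named in advance, Actb, Hprt1, Ptgs2 and Tnc differed from control by less than 2-fold on each day by the probe sets read for them. The reference gene Actb was 1.16-fold, 1.15-fold and 1.21-fold higher at days 3, 7 and 25, and at day 3 it was lower under quantile normalization, cyclic loess and the values as deposited. Hprt1, the other reference gene, was 1.54-fold higher, 1.51-fold lower and 1.86-fold higher. It was not steady across the injured bladders, going from 579 at day 7 to 1623 at day 25. Ptgs2, inducible cyclooxygenase, was 1.78-fold higher at day 3 and differed 1.10-fold and 1.09-fold afterwards. Tnc was 1.27-fold lower, 1.09-fold higher and 1.47-fold lower. Other probe sets of Hprt1, Ptgs2 and Tnc went the other way on some days, that of Tnc from 149 to 435 at day 3. Igf1 was 3.84-fold, 2.13-fold and 2.20-fold higher, with another probe set slightly lower at days 7 and 25. Il6 and Mmp9 were at the floor on all 4 arrays.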

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

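The tests of explanations in this part were all chosen after the results they bear on had been seen.

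Among the genes named by rule, 7 were at least 2-fold higher than control at one time and at least 2-fold lower at another. These differences between times were not tested, since each time is 1 bladder. On the log2 scale Actc1 differed from control by 2.42 at day 3, -1.01 at day 7 and -1.13 at day 25. Cacna2d1 differed by -2.30 at day 3 and 1.09 at day 25, the latter under 2-fold in all 4 other scalings, and Triobp by 1.38 and -1.27. Ccnd2 differed by -2.06 at day 3, 1.65 at day 7 and 1.27 at day 25, although another of its probe sets was lower at the later days and the mean of its probe sets gave less than 2-fold. Crp differed by -1.03 at day 3 and 1.93 at day 25 by the probe set read for it, the former reversed by the mean of its probe sets. As said above, the pairing of these probe sets with Crp was not checked. Igfbp6 differed by 1.08 at day 3, under 2-fold in all 4 other scalings, and by -1.79 at day 7. RT1-Bb differed by 2.02 at day 3, -1.38 at day 7 and 2.92 at day 25, with another probe set higher at day 7, and the mean of its probe sets gave less than 2-fold at day 3 and was at the floor on the control array and at the later days.

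The array's own control probe sets, which enter no comparison, had a higher ratio of 3′ to 5′ intensity on each injured bladder than on the control. For Gapdh the ratio was 2.03 at day 3, 4.09 at day 7 and 7.02 at day 25, against 1.05. For beta-actin it was 30.5, 50.5 and 70.9, against 23.1. The ratio of the 3′ end to the middle of the transcript was higher than on the control for beta-actin, at 3.74 against 0.72 at day 25. For Gapdh it was not, at 0.93 against 1.01. Less intact RNA or shorter cDNA would give higher 3′ to 5′ ratios and could lower genes whose probe sets lie far from the 3′ end. If it were the whole cause of the genes at least 2-fold lower than control, their number should grow with the 3′ to 5′ ratio. The count at day 25 minus that at day 3 was -122, and the count was lower at day 25 under all 9 settings in which it was recounted. A part of these decreases from RNA quality stays open, because the position of each probe set on its transcript was not used here, and the injury itself stays open for the rest as untested. Aldoa, at 1989, 372, 145 and 42 on the control, day 3, day 7 and day 25 arrays, fell as the ratio rose. So did Cald1, at 1178, 229, 169 and 53. Both were singled out after their values had been seen, and for both loss of 5′ signal cannot be told apart from a change after injury.

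Urothelial markers were higher in all 3 injured bladders although the muscle layer had been dissected. The lowest percentile of the list over the 3 days and 4 other scalings was 99.33. That percentile ranks the list against genes of like level on the same arrays, which a scaling moves too. It therefore cannot test scaling as a cause of the increases, and shows only that the list stood above such genes under each scaling. More urothelium of one composition left on the muscle would move every marker by one factor between days. From day 3 to day 7 the 10 markers above the floor on both arrays had an SD of 0.87 (log2), from -0.68 for Krt18 to 1.87 for Epcam, against 0.59 between probe sets of 1 gene, which is too close to settle it. None of the 14 markers on the array is in another fixed list, but 11 were above the floor in the control muscle, and the 2 most abundant at day 3 moved unequally, Sprr1a from 3204 to 4789 and Krt5 from 284 to 3279, so that more residual urothelium, thicker urothelium after injury and keratin expression by other cells all remain possible. The list did not stand apart at day 3 with the floor at the 20th percentile, and Epcam and Krt18 were singled out after their values had been seen.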

How the results depend on the processing

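No paired analysis was possible because each group is 1 bladder and the labels number no replicates, and for the same reason no replicate could be left out. The alternatives were planned before the data were examined, except centring on probe sets above the floor on all 4 arrays and leaving out day 25. Of 92 recounted gene totals, 55 stayed within 1.5 times the main count. Of 222 recomputed medians of lists that stood apart from control, 199 still stood apart on the same side and none turned, and 33 medians of lists that had not stood apart did so under an alternative. Of 2370 recomputed changes of named genes, 2276 moved by less than the SD between probe sets, 91 moved by more and 3 reversed. Except where a setting admits fewer or dimmer genes by its construction, the cause was not tested.

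With the floor at the 20th percentile, which admits dimmer genes, genes at least 2-fold lower were 650 at day 3, higher and lower were 581 and 587 at day 7, 680 and 561 at day 25, 614 and 618 between day 25 and day 3, and 209 and 135 on all 3 days. At the 60th percentile 191 were lower at day 3, and higher and lower were 158 and 147 at day 7, 258 and 111 at day 25, and 173 and 147 between day 25 and day 3, with 41 lower on all 3 days. As deposited, day 3 had 355 higher and 577 lower, day 25 had 430 lower, and 128 were lower on all 3 days. Counting only genes above the floor on both arrays left 251 lower at day 3, 204 higher and 209 lower at day 7, 159 lower at day 25 and 31 lower on all 3 days. At 3-fold there were 207 and 141 at day 3, 102 and 99 at day 7, 153 and 83 at day 25, 120 and 63 between day 25 and day 3, and 39 and 20 on all 3 days. Without day 25, 174 genes were higher and 143 lower on both other days.

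Lists that stood apart in the comparisons with control and no longer did so had these medians (log2). With the floor at the 20th percentile they were the response to bacteria at day 3 (0.54), immediate early genes at day 25 (0.41) and urothelium at day 3 (0.71). With the floor at the 60th they were smooth muscle at day 25 (-0.068), the response to bacteria at day 3 (0.56), antigen presentation at days 3 and 7 (0.79 and 0.39), immediate early genes at day 25 (0.41) and sterol synthesis at day 7 (0.46). Smooth muscle at day 25 also lost its place as deposited (-0.32), under quantile normalization (-0.18), under cyclic loess (-0.30) and centred on probe sets above the floor (-0.20), and the response to bacteria at day 3 as deposited (0.21), under quantile normalization (0.33) and under cyclic loess (0.34). With the mean of all probe sets, fibrillar collagens at day 3 (0.84), matrix proteases at day 3 (0.64), inflammatory mediators at day 25 (0.41), the response to bacteria at day 3 (0.54), immediate early genes at day 25 (0.46), sterol synthesis at day 7 (0.35) and fibroblasts at day 7 (0.074) did not stand apart. For day 25 against day 3, lists lost their place for detrusor receptors under both other floors and cyclic loess, for smooth muscle with the floor at the 60th percentile, quantile normalization, cyclic loess and the mean of all probe sets, for elastic fibres with the floor at the 20th, quantile normalization and the mean of all probe sets, for neutrophils with the floor at the 60th and for inflammatory mediators with the mean of all probe sets. That mean also reversed Crp at day 3 to 0.39, Fosl2 at day 7 to -0.27 and Nefl at day 3 to 0.090. Signal over background limits the dim genes most, as 40% of all probe set values lay at the floor.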

Other observations

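Several fixed lists that did not stand apart from matched lists against control on any day still held large single differences. With the floor at the 20th percentile growth factors stood apart at day 3, at percentile 97.86, and with the mean of all probe sets heat shock genes were lower at day 3, at 0.89, and fatty acid oxidation genes at days 3 and 25, at 1.36 and 2.17. Among antioxidant genes, with medians of 0.48, 0.15 and 0.50 at days 3, 7 and 25, Hmox1, heme oxygenase, was 7.85-fold, 4.73-fold and 3.99-fold higher and Sod2 was 4.10-fold higher at day 25, while Cat, catalase, was 4.54-fold lower at day 3. Gstp1 was 4.02-fold lower at day 3, with another probe set higher. Glycolysis and hypoxia-response genes had medians of 0.20, 0.19 and 0.28. Slc2a1, the glucose transporter, was 2.42-fold, 3.13-fold and 3.37-fold higher and Pkm 3.45-fold higher at day 3 and Pfkl 3.27-fold higher at day 7, whereas Aldoa was 5.35-fold lower at day 3 and at least 21.4-fold lower at day 25. Growth factors and their binding proteins had medians of 0.14, 0.20 and 0.20, with Tgfb3 6.23-fold higher at day 3. Igfbp5 was 4.23-fold lower at day 25 by its brightest probe set and higher by another. Among glucocorticoid-response genes, with medians of 0.54, 0.05 and 0.39, Sgk1 was 5.41-fold, Cebpb 5.13-fold and Dusp1 3.72-fold higher at day 3, and Anxa1 was 5.07-fold higher at day 25. Heat shock and unfolded protein response genes had medians of 0.03, 0.10 and 0.47, with Hspb1 2.52-fold higher at day 3, Hspa5 2.61-fold higher at day 25 and Ddit3 at least 2.49-fold lower at days 3 and 7. Fatty acid oxidation genes had medians of -0.17, -0.14 and -0.29, with Acadm 2.11-fold lower at day 3, Cpt1b 2.65-fold lower at day 7 and Acaa2 2.05-fold lower at day 25. Slc25a20 was at least 2.52-fold lower at day 3. The day 3 medians of the glycolysis, growth factor, heat shock, nerve, skeletal muscle and adipose lists turned negative in the values as deposited.

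Markers of other cells did not stand apart from matched lists in the comparisons with control under the main processing. Under alternatives some did: T and NK cell genes at day 25, endothelial genes on all 3 days and mast cell genes at day 25 were higher in 1 or more of them, and skeletal muscle genes at day 7 were lower. Endothelial genes had medians of 0.34, 0.39 and 0.59, with Ace at least 4.46-fold and Egfl7 and Kdr 3.02-fold higher at day 3 and Aqp1 2.75-fold higher at day 25. T and NK cell genes had medians of -0.20, 0.21 and 0.31, with Cd8a at least 3.20-fold and Lck 2.39-fold higher at day 25. Mast cell genes had medians of 0.44, -0.07 and 0.44, with the chymase Cma1 3.44-fold and Cpa3 1.41-fold higher at day 3, and Cpa3 2.66-fold higher at day 25. Schwann cell and nerve genes had medians of 0.22, -0.32 and -0.22. Cnp, a myelin enzyme, was 4.68-fold higher at day 3 and Chat, which makes acetylcholine, was at least 2.78-fold lower. Skeletal muscle genes had medians of 0.14, -0.33 and 0.26, with Acta1 3.87-fold and Tnnt3 2.89-fold higher at day 3. Adipose genes had medians of 0.15, -0.07 and 0.26, with Cfd, adipsin, 5.04-fold and Lpl 6.52-fold higher at day 25 and Me1 3.97-fold higher at day 3, with another probe set lower. Of the B and plasma cell genes 2 were compared, too few to place, and Cd37 was 2.92-fold, 2.88-fold and 3.36-fold higher. Of the neutrophil markers 4 were compared at day 3, also too few, among them Cxcr1 at least 3.41-fold higher and Padi4 at least 2.88-fold lower. That list could be placed at day 3 with the floor at the 20th percentile, and lay at percentile 99.48.

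The circadian clock genes Nr1d1, Nr1d2, Dbp, Per2 and Bhlhe41 were lower in all 3 injured bladders, a pattern noticed in the data, and both tests of it were chosen after it had been seen, as were Dbp, Per2 and Bmal1. Nr1d1 was lower by a log2 difference of -2.92, -2.63 and -2.94 at days 3, 7 and 25. Nr1d2, Dbp and Bhlhe41 were lower as well, the smallest of their differences being -1.95 for Dbp at day 7, and Per2 was lower by -0.55 at day 7 and by a bound of -1.55 on the other days. A candidate explanation is that the injured rats' tissue was taken at another phase of the clock. Bmal1, whose daily cycle opposes that of Nr1d1, was higher by the probe set read for it. Its changes were at least 0.81 at day 3, 1.03 at day 7 and 2.63 at day 25, all bounds because it was at the floor in the control bladder. Another Bmal1 probe set was below the floor on the control, day 3 and day 7 arrays and at 229 at day 25, so it shows no increase at days 3 and 7. Tef, another gene under clock control, changed by -0.12, 0.06 and -0.32. Bhlhe40 was lower by a bound of -0.86 at day 3, by -0.52 at day 7 and by -0.54 at day 25, and Hlf was at the floor on all arrays but that of day 25. Loss of 5′ signal cannot be told apart for part of the pattern. Nr1d1 changed by -0.03 from day 3 to day 25 while the Gapdh 5′ to 3′ signal changed by -1.79. However, another Nr1d1 probe set, at the floor at day 25, changed by a bound of -1.03, and Bhlhe41 by a bound of -1.82. Times of day of collection are not given in the sources used here, and a changed clock after injury stays open as untested.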
